A study of Homo sapiens with 6 samples.

How the data were processed

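Total RNA of 6 LS174T samples was labelled with Cy3 and hybridised to Agilent one-colour arrays: 2 not transfected, 2 overexpressing active ATF6a and 2 overexpressing active ATF6b, all labelled as treated with 2 mM sodium butyrate. The arrays were scanned and read by the authors with Agilent Feature Extraction 10.7.1.1, and the deposited scanner files give per spot a processed signal as an intensity, after background subtraction and detrending per the file headers, together with the median spot and local background intensities. No normalization between arrays had been applied to those intensities. The authors also deposited a matrix of processed values, whose scale is not stated; the values fit a log2 scale, since their differences between arrays correlated at 0.996 to 0.999 with differences of the log2 scanner signal shifted to each array's 75th percentile. The value on which the authors centred each probe in that matrix is not given in the sources used here. The file headers name array design 028004 and genome build hg19. Gene positions were not used. How the ATF6a and ATF6b constructs were delivered, the times of transfection and treatment, and whether replicates were separate cultures are not given in the sources used here.

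Each array had 58717 non-control spots for 42405 probes. The log2 processed signal was reduced by the log2 of the array's 75th percentile over non-control spots, outlier spots (253 to 309 per array) were left out, and spots of a probe were averaged. RefSeq accessions of the probes were matched to gene symbols through a reference table, which named 25422 probes. The other 16983 kept the accession or name in the files as identity. A probe counted as above background on an array when at least 0.5 of its spots were called well above background by Feature Extraction. Probes above background on both arrays of at least 1 group were kept (27173), and the probe with the highest mean over all 6 arrays stood for its gene. This gave 22573 genes, 14517 with a symbol and 8056 without, with 12 missing values.

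Groups were compared with limma 3.58.1 in R 4.3.3 (with the data.table package, 1.17.8) in 1 fit with all 3 groups, moderated variances without trend, two-sided tests and contrasts for ATF6a against untransfected, ATF6b against untransfected and ATF6b against ATF6a. The fit had 3 residual and 2.15 prior degrees of freedom. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Genes that were not above background on any array of the dimmer group were given a fold as a bound: the brighter group's mean against the dimmer group's mean after raising each of its arrays to the lowest signal called above background on that array. No fold is given where both groups were in that state, and a log2 value of such a gene only where a setting reversed its sign. Both fold changes against untransfected share the same 2 arrays, so their correlation, covariance and sign agreement are given beside values from 100 simulated sets of 3 unchanged groups (seed 1) with the spread of the data.

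In total 16 gene lists with 268 members were fixed before the data were examined, from textbook knowledge of the unfolded protein response, colon cell types, other cell types and responses to transfection: ER chaperones and folding enzymes, ER-associated degradation, ER translocation and vesicle transport, PERK-ATF4-CHOP arm, goblet cell markers, mucin O-glycosylation, absorptive enterocyte markers, enteroendocrine markers, intestinal stem cell and Wnt targets, cell cycle, interferon response, NF-kB and chemokines, cytosolic heat shock, p53 targets and apoptosis, sterol and fatty acid synthesis, and non-epithelial cell markers. For 5 members no probe was matched through the reference table (MUC5AC, PAX4, UBE2C, IFI27 and NFKB2), which leaves open whether a probe kept under its accession alone measures them, 26 were not above background and 237 were measured. Lists were tested with camera of limma, which compares a list with all other genes, at a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over the 16 lists of a comparison. The estimated version tests on the 3 residual degrees of freedom of the fit and the preset version does not, so few lists can pass it. For the absorptive list with ATF6a the estimated correlation was 0.015, close to the preset. Its unadjusted camera p was still 0.0401, against 0.00032 with the preset. Failing the estimated version therefore does not by itself show that correlation between genes made a result. For the sterol list with ATF6a, however, the estimated correlation was 0.337, and the unadjusted camera p went from 0.00060 to 0.262. There correlation between genes also weakened the result. Genes of a list were counted with p adjusted over all genes and adjusted over the list alone.

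The named genes followed a rule fixed before the data were examined. For each comparison with untransfected cells it took the 10 largest increases and 10 largest decreases among called genes with a symbol whose arrays did not overlap between groups, and 5 and 5 for ATF6b against ATF6a. ATF6, ATF6B and up to 4 members of each list with the largest absolute change were added. Genes named outside the rule are marked as such.

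The steps were tested on simulated data with the spread of these arrays over 22561 genes. For ATF6b against ATF6a, 61.2% of 67 genes changed 2-fold, 83.6% of 67 changed 4-fold and 100% of 66 changed 16-fold were recovered, with 12 false calls among 175. Against untransfected the shares were 64.2%, 79.1% and 98.5% for ATF6a with 9 false calls, and 61.2%, 80.6% and 98.5% for ATF6b with 5 false calls. Camera called 1 of 16 lists, the shifted one. That simulation drew genes independently, so false list calls from correlation between genes could not appear in it. In the data the estimated correlation reached 0.471, for the NF-kB and chemokine list. The limma simulations changed only the genes counted here, far fewer than the 15262 and 14686 called against untransfected cells in the data. Their shares and false calls therefore do not describe those comparisons, where the cut-off on unadjusted p was more lenient.

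The alternatives were the replicate number as a block, normexp background correction (offset 50), quantile normalization, no filter on dim probes, probes above background on all 6 arrays, the mean of a gene's probes, the authors' log2 matrix, an intensity trend in the prior, a fit with only the groups compared, leaving out each array in turn, and an estimated correlation in camera. Normexp used the median spot signal because the files hold no mean signal. Scaling on the spiked-in control RNA and keeping the outlier spots were added after the data were seen. Probe positions relative to the transgenes were not examined, and control spots were used only for the spike-in values. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.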

Results

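LS174T is a human colon adenocarcinoma line that makes intestinal mucin. Total RNA from 6 samples of it was measured on Agilent one-colour arrays in 3 groups of 2. One group was not transfected, one overexpressed active ATF6a and one overexpressed active ATF6b. Both proteins are transcription factors of the unfolded protein response: stress in the endoplasmic reticulum (ER) releases their active part, which moves to the nucleus. The labels state the same treatment for all 6 samples, although the titles call the untransfected ones Tx- without saying what this stands for: 2 mM sodium butyrate, a histone deacetylase inhibitor that drives LS174T cells toward a goblet cell state. No group that received an empty vector was among the samples, so each overexpression was set against cells that had not been transfected at all.

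The 6 arrays lay on 1 slide, with the untransfected, ATF6a and ATF6b samples in columns 2, 3 and 4, so group and slide column could not be separated. Replicate 1 of each group lay in row 1 and replicate 2 in row 2. Between 59.2% and 62.3% of probes were above background, and the 75th percentile of signal was between 516 and 634 intensity units. No spot was saturated. After filtering, 22573 genes were tested, 14517 of them with a gene symbol. Replicates of a group differed by a median absolute log2 value of 0.115 in untransfected, 0.123 in ATF6a and 0.122 in ATF6b samples. The number of arrays limits the precision. The labels do not say whether replicates were separate cultures, so the p-values measure only the spread between these samples, which could be technical. Errors after ± are standard errors of the log2 change from limma, with n = 2 arrays per group, and adjusted p is the Benjamini-Hochberg value over all genes tested unless stated otherwise.

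The first comparison asked which genes differed between cells overexpressing ATF6a and untransfected cells. All 21 measured members of the cell cycle list fell, with a median 18.2-fold decrease, and all 14 measured interferon-response genes rose, with a median 7.16-fold increase. Absorptive enterocyte markers rose in 13 of 16 members, and sterol and fatty acid synthesis genes rose in 14 of 20 and fell in 1. These 4 lists passed camera with its preset correlation but not with an estimated correlation (adjusted p = 0.214 for the first 3 and 0.819 for the last). The estimated version rests on 3 residual degrees of freedom, so failing it does not by itself show that correlated genes made these results. Estimated correlations were 0.015 for absorptive, 0.060 for interferon and 0.179 for cell cycle genes, but 0.337 for sterol and fatty acid synthesis genes. Correlation between genes therefore weakened the sterol result more than the other 3. Of the 22573 genes, 15262 (67.6%) passed the test, 7895 higher and 7367 lower, and 3340 of the higher and 3484 of the lower ones differed by 2-fold or more.

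The largest increases belonged to genes with little or no signal in untransfected cells. ATP8B3 (NM_138813), a member of the family of phospholipid-flipping ATPases, was at least 199.6-fold higher (log2 change 7.64 ± 0.22, adjusted p = 2.8e-05). HBA2, an alpha-globin gene with a nearly identical neighbour that its probe may also detect, rose by 6.18 ± 0.18 on the log2 scale. CREB3L3, an ER-anchored transcription factor of liver and intestine, rose by 6.07 ± 0.10 (67.0-fold, adjusted p = 2.5e-05). The actin-binding gene SYNPO rose by 5.88 ± 0.15, C11orf86 by 5.77 ± 0.10 and KLC3, a kinesin light chain, by 5.63 ± 0.28. EEF1A2, a translation elongation factor, was at least 35.7-fold higher and MAPT, which encodes tau, at least 26.0-fold higher. The antiviral genes IFIT1 (6.04 ± 0.20) and MX2 (at least 50.2-fold) completed the top 10.

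Among the 10 largest decreases, SPC25 and NUF2, parts of the kinetochore, were at least 143.1-fold and at least 90.3-fold lower, and CENPE, a kinetochore motor, changed by -6.70 ± 0.24 on the log2 scale. The spindle checkpoint kinase TTK was at least 69.7-fold lower and ANLN, needed for cytokinesis, at least 67.3-fold lower. The histone genes H3C15 (-6.71 ± 0.25) and H1-5 (at least 76.4-fold lower) fell too, as did CABP7 (at least 86.4-fold lower) and DDIAS (at least 72.8-fold lower). DEFA6, a Paneth cell defensin, had the largest fitted decrease, at least 147.8-fold (log2 change -7.21 ± 1.73, adjusted p = 0.0144). Its call ended when either untransfected or either ATF6a array was left out, with an adjusted p of up to 0.0600 while the log2 change stayed between -7.45 and -6.96. Its arrays had an SD of 0.0567 in untransfected and 0.348 in ATF6a samples, so the standard error came mainly from the ATF6b arrays in the same fit (SD 3.90).

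Cell cycle genes gave the strongest list result with ATF6a (21 of 21 lower, median -4.18, camera adjusted p = 8.1e-12, and adjusted p = 0.214 with an estimated correlation). CDK1, the kinase of mitotic entry, changed by -6.14 ± 0.15, its partner CCNA2 by -5.94 ± 0.13, TOP2A by -5.61 ± 0.11 and RRM2, which makes deoxyribonucleotides, by -5.39 ± 0.28. In the interferon list the median was 2.84 (14 of 14 higher, adjusted p = 2.0e-06, and adjusted p = 0.214 with an estimated correlation). IFI6 rose by 5.59 ± 0.10, MX1 by 3.96 ± 0.09 and OASL by 3.30 ± 0.11.

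Absorptive enterocyte markers rose in 13 of 16 measured members and fell in 0 with ATF6a, and 3 did not pass. The list median was 1.07, or 0.96 with dim members at their bound (adjusted p = 0.00172, and adjusted p = 0.214 with an estimated correlation). KRT20, a keratin of mature surface cells, rose by 3.80 ± 0.49, the brush border cadherin CDHR5 by 3.72 ± 0.10 and carbonic anhydrase CA1 by 2.63 ± 0.18, and the chloride exchanger SLC26A3 was at least 2.84-fold higher. Sterol and fatty acid synthesis genes rose in 14 of 20 members and fell in 1, with a median of 0.53 (adjusted p = 0.00238, and adjusted p = 0.819 with an estimated correlation). Fatty acid synthase FASN rose by 2.68 ± 0.11, INSIG1 by 2.67 ± 0.09 and SREBF1, a regulator of lipid synthesis, by 2.38 ± 0.09.

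Known targets of the ER stress response went both ways with ATF6a, and none of their lists passed the list test. Of 19 ER chaperones and folding enzymes, 10 rose, 3 fell and 6 did not pass (median 0.32, adjusted p = 0.328). The chaperone HSPA5 rose by 1.36 ± 0.08, CRELD2 by 1.64 ± 0.09, and the disulfide isomerases P4HB and PDIA4 by 1.14 ± 0.07 and 1.12 ± 0.10. Of 17 genes of ER-associated degradation, 7 rose and 5 fell (median 0.05, adjusted p = 0.684), with HERPUD1 up by 1.34 ± 0.08, the ubiquitin ligase SYVN1 by 1.26 ± 0.09 and OS9 by 1.15 ± 0.08. Of 16 genes of ER translocation and vesicle transport, 2 rose and 7 fell (median -0.09, adjusted p = 0.583). The signal peptidase subunit SPCS3 changed by -1.21 ± 0.10 and the coat protein gene SEC31A by 0.97 ± 0.10. In the PERK-ATF4-CHOP arm 8 of 16 genes rose and 5 fell (median 0.42, adjusted p = 0.583). CHAC1 rose by 1.92 ± 0.08 and ATF3 by 1.36 ± 0.18, whereas ATF5 changed by -2.48 ± 0.09.

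Goblet cell markers split with ATF6a: 7 of 20 rose and 11 fell (median -0.35, adjusted p = 0.583). The goblet lectin ZG16 changed by -4.86 ± 0.55 and RETNLB by -3.48 ± 0.15, and ATOH1, the transcription factor of the secretory lineage, and CLCA1 were at least 5.55-fold and at least 5.50-fold lower. The secreted mucins of the list that were measured rose instead, MUC2 by 2.37 ± 0.09 and MUC5B by 2.30 ± 0.12; this pair was chosen after its values were seen. Among 14 mucin O-glycosylation genes 6 rose and 4 fell (median -0.08, adjusted p = 0.684), with the sulfotransferase CHST5 up by 3.57 ± 0.11 and ST3GAL1 by 1.65 ± 0.09. Stem cell and Wnt target genes rose in 3 and fell in 7 of 15 members (median -0.21, adjusted p = 0.328). OLFM4 and LGR5, markers of crypt stem cells, changed by -5.83 ± 0.61 and -4.11 ± 0.11, and ASCL2 by -2.35 ± 0.10. Of 5 enteroendocrine markers 1 rose and 2 fell (median -0.44, adjusted p = 0.583), and the hormone granule gene CHGA was at least 2.39-fold lower. The call of SCG2, the other that fell, ended under 5 settings (adjusted p up to 0.124).

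The remaining lists did not pass the list test with ATF6a. In the NF-kB and chemokine list 6 of 11 genes rose and 4 fell (median 0.83, adjusted p = 0.616), with the adhesion gene ICAM1 up by 2.73 ± 0.08 and the chemokine CXCL8 changed by -2.90 ± 0.21. Cytosolic heat shock genes rose in 6 and fell in 6 of 12 members (median 0.04, adjusted p = 0.979), and HSPB1 rose by 2.02 ± 0.08. Of 13 p53 targets and apoptosis genes 7 rose and 4 fell (median 0.26, adjusted p = 0.651). The cell cycle inhibitor CDKN1A rose by 3.26 ± 0.11 and PMAIP1 changed by -2.19 ± 0.10. Of 8 measured markers of non-epithelial cells 4 rose and 2 fell (median 0.98, adjusted p = 0.469), COL1A1 at least 6.0-fold higher, CD68 up by 3.34 ± 0.09 and LUM at least 3.75-fold lower.

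In total 4 of the 16 lists passed camera with its preset correlation for ATF6a and 0 passed with an estimated correlation, where 3 had an unadjusted p under 0.05. Adjusted over the list alone, the gene counts differed for only 2 of the 16 lists: 6 ER translocation genes fell instead of 7, and 8 goblet markers rose instead of 7. The medians of the mucin O-glycosylation and heat shock lists had the opposite sign to their camera test, and neither list was called. The arrays of both groups did not overlap for 19141 genes (84.8%, against 33.3% by chance). Of 2861 called genes with more than 1 measured probe, 197 had another probe that itself passed in the opposite direction.

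**Figure D1:**
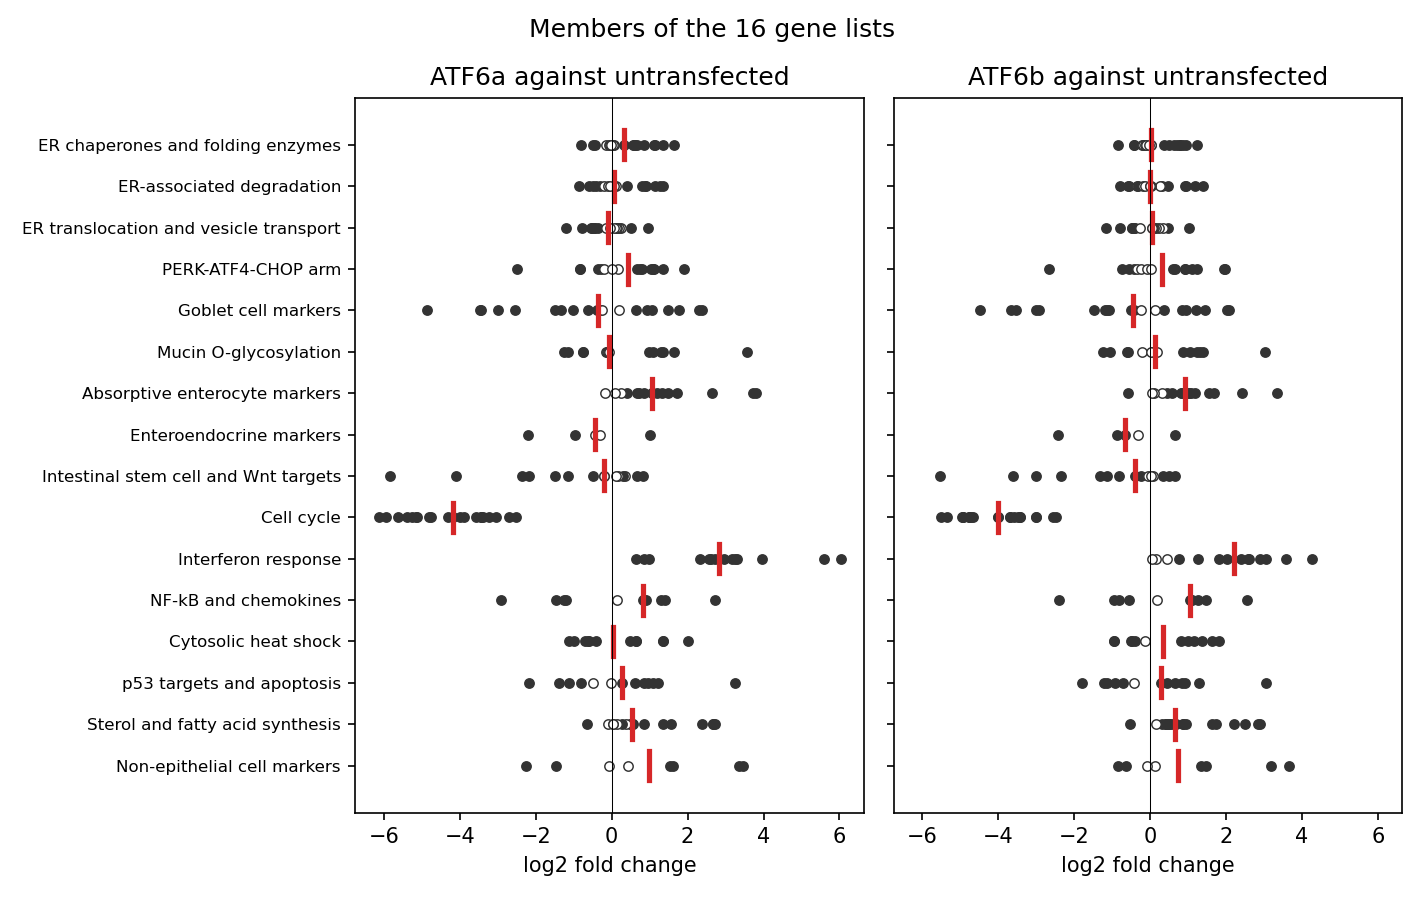
Log2 fold change of each measured member of the 16 lists for ATF6a and for ATF6b against untransfected cells, with filled dots for genes past an adjusted p of 0.05, open dots for the others and a red bar at the median of each list. Cell cycle genes lie farthest to the left (medians -4.18 and -4.01) and interferon genes farthest to the right (2.84 and 2.21).

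The second comparison asked the same question for ATF6b. Cell cycle genes fell in 21 of 21 measured members (median 16.1-fold decrease), interferon genes rose in 11 of 14, absorptive markers rose in 12 of 16 and fell in 1, and sterol and fatty acid synthesis genes rose in 18 of 20 and fell in 1. These lists again passed camera with its preset correlation but not with an estimated correlation (adjusted p = 0.253 for the first 3 and 0.691 for the last). Of the 22573 genes, 14686 (65.1%) passed the test, 7291 higher and 7395 lower. At 2-fold or more were 2881 of the higher and 3223 of the lower ones. This split depended on the processing, with 6949 higher and 3642 lower under spike-in scaling and 6684 and 8819 under normexp.

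ATP8B3 again had the largest increase, at least 190.1-fold, followed by HBA2 with a log2 change of 6.94 ± 0.18. EEF1A2 was at least 33.0-fold higher. CREB3L3 rose by 5.85 ± 0.10, SYNPO by 5.68 ± 0.15, C11orf86 by 5.57 ± 0.10 and KLC3 by 5.51 ± 0.28. The metalloproteinase inhibitor TIMP2 rose by 5.50 ± 0.13 and the reticulon RTN2 by 5.48 ± 0.15, and the adaptor gene SH2D3C was at least 27.5-fold higher. The largest decreases included H3C15 (-6.77 ± 0.25), SPC25 (-6.44 ± 0.27), HJURP, which loads the centromeric histone (-5.92 ± 0.12), and the helicase PIF1 (-5.94 ± 0.24). CABP7 was at least 101.9-fold lower, H1-5 at least 77.3-fold, TTK at least 77.2-fold, the DNA polymerase POLQ at least 61.9-fold and the mitotic kinesin KIF18A at least 45.1-fold. DEFA6 changed by -6.80 ± 1.73, but with the wide spread of its ATF6b arrays its call ended without either untransfected array, with an adjusted p of up to 0.0692.

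With ATF6b the cell cycle list had a median of -4.01 (camera adjusted p = 9.2e-12, and adjusted p = 0.253 with an estimated correlation), with CDK1 at -5.51 ± 0.15, CCNA2 at -5.34 ± 0.13 and BUB1, a spindle checkpoint kinase, at -4.94 ± 0.18. The interferon list had a median of 2.21 (adjusted p = 4.7e-05, and adjusted p = 0.253 with an estimated correlation). IFIT1 rose by 4.27 ± 0.20, IFI6 by 3.59 ± 0.10 and OASL by 3.06 ± 0.11, and 3 of its genes did not pass, among them IFI44 with a value of 0.43 and RIGI with 0.16. The absorptive list had a median of 0.93, or 0.84 with dim members at their bound, with 12 genes higher and 1 lower (adjusted p = 0.00312, and adjusted p = 0.253 with an estimated correlation). CDHR5 rose by 3.35 ± 0.10, KRT20 by 2.43 ± 0.49 and CA1 by 1.56 ± 0.18. The apolipoprotein gene APOA4 was at least 1.91-fold higher, although its log2 change was -0.013 with another background correction (normexp). Sterol and fatty acid synthesis genes had a median of 0.65, with 18 higher and 1 lower (adjusted p = 4.7e-05, and adjusted p = 0.691 with an estimated correlation). INSIG1 rose by 2.91 ± 0.09 and SREBF1 by 2.20 ± 0.09.

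ER stress lists again went both ways with ATF6b. Of 19 ER chaperones and folding enzymes 9 rose and 3 fell (median 0.02, adjusted p = 0.467), HSPA5 by 1.23 ± 0.08, CRELD2 by 0.94 ± 0.09 and the co-chaperone DNAJB9 by 0.88 ± 0.07. TXNDC5 changed by -0.85 ± 0.10, a call that ended with arrays scaled on spiked-in control RNA (adjusted p = 0.0942). Among genes of ER-associated degradation 6 of 17 rose and 4 fell (median 0.0021, adjusted p = 0.634), with HERPUD1 up by 1.41 ± 0.08 and SYVN1 by 1.18 ± 0.09. ER translocation genes rose in 2 and fell in 6 of 16 members (median 0.05, adjusted p = 0.634), with SPCS3 at -1.16 ± 0.10 and SEC31A at 1.02 ± 0.10. The PERK-ATF4-CHOP arm had 8 of 16 genes higher and 4 lower (median 0.31, adjusted p = 0.550), ATF3 by 1.98 ± 0.18, CHAC1 by 1.94 ± 0.08 and ATF5 by -2.66 ± 0.09.

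Goblet markers rose in 7 and fell in 11 of 20 members with ATF6b (median -0.46, adjusted p = 0.467). ZG16 changed by -4.48 ± 0.55 and RETNLB by -3.54 ± 0.15, ATOH1 and CLCA1 were at least 6.16-fold and at least 6.52-fold lower, and the mucin pair named above rose, MUC2 by 2.09 ± 0.09 and MUC5B by 2.03 ± 0.12. Of 14 mucin O-glycosylation genes 6 rose and 4 fell (median 0.12, adjusted p = 0.467), CHST5 by 3.04 ± 0.11. Stem cell and Wnt targets rose in 3 and fell in 9 of 15 members (median -0.40, adjusted p = 0.160), with OLFM4 at -5.53 ± 0.61, LGR5 at -3.61 ± 0.11 and ASCL2 at -3.01 ± 0.10. Of 5 enteroendocrine markers 1 rose and 3 fell (median -0.65, adjusted p = 0.467), and CHGA was at least 2.65-fold lower. The calls of the others that fell ended under 10 settings for SCG2 and 3 for GCG (adjusted p up to 0.169 and 0.286).

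In the NF-kB and chemokine list 6 of 11 genes rose and 4 fell with ATF6b (median 1.04, adjusted p = 0.467), with ICAM1 at 2.55 ± 0.08 and CXCL8 at -2.40 ± 0.21. Heat shock genes rose in 6 and fell in 5 of 12 members (median 0.34, adjusted p = 0.634), HSPB1 by 1.81 ± 0.08. Of 13 p53 targets and apoptosis genes 7 rose and 5 fell (median 0.28, adjusted p = 0.634), CDKN1A by 3.05 ± 0.11. Of 8 markers of non-epithelial cells 4 rose and 2 fell (median 0.74, adjusted p = 0.335), with COL1A1 at least 6.90-fold higher and CD68 up by 3.18 ± 0.09. Adjusted over the list alone, the counts were the same for all 16 lists. Camera called 4 of the 16 lists with its preset correlation and 0 with an estimated one, where 3 had an unadjusted p under 0.05; the ER translocation list, not called, had a median opposite in sign to its test. The arrays did not overlap for 18940 genes (83.9%, against 33.3% by chance). Of 2778 called genes with more than 1 measured probe, 205 had another probe that itself passed in the opposite direction.

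Probes for the overexpressed genes themselves check nothing about the transgenes, since the labels do not say which part of each gene was expressed. The titles read mATF6aOE and mATF6bOE without saying what the m stands for. These arrays therefore leave the overexpression itself unchecked. The ATF6 probe changed by -0.55 ± 0.08 with ATF6a (adjusted p = 0.00220) and by -0.48 ± 0.08 with ATF6b (adjusted p = 0.00385). Both calls ended with arrays scaled on spiked-in control RNA (limma adjusted p = 0.0945 and 0.573). The log2 change under that scaling was -0.58 with ATF6a, no smaller than before, and -0.22 with ATF6b. The ATF6B probe rose by 0.81 ± 0.11 (adjusted p = 0.00167) and 0.58 ± 0.11 (adjusted p = 0.00623). Between ATF6b and ATF6a samples the values were 0.07 ± 0.08 for ATF6 (adjusted p = 0.682) and -0.23 ± 0.11 for ATF6B (adjusted p = 0.358).

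The third comparison, of ATF6b with ATF6a, tested the difference between both overexpressions directly. Of 14 interferon-response genes 2 were lower with ATF6b and 12 did not pass (list median -0.82, camera adjusted p = 2.1e-11, and adjusted p = 0.176 with an estimated correlation). IFI6 changed by -2.00 ± 0.10 (adjusted p = 0.0210), the interferon-induced XAF1 by -2.21 ± 0.13 (adjusted p = 0.0214) and MX1, an antiviral GTPase, by -1.39 ± 0.09 (adjusted p = 0.0294). Of the 22573 genes 39 passed the test, 19 higher and 20 lower with ATF6b, and 37 of them differed by 2-fold or more. At an unadjusted p under 0.05 there were 3525 genes.

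Besides the interferon genes, the homeobox gene OTP was at least 5.79-fold lower with ATF6b (log2 change -3.21 ± 0.10, adjusted p = 0.00732), although with normexp background correction its change was -0.61. KLHDC7B changed by -1.53 ± 0.10 (adjusted p = 0.0311; -1.0 with normexp) and the scavenger receptor gene SCARF2 by -1.48 ± 0.12 (adjusted p = 0.0405). XAF1 also had a smaller change with normexp, -1.26. In the other direction TMEM151B was higher with ATF6b by 2.76 ± 0.11 (6.79-fold, adjusted p = 0.0125). PON3, a paraoxonase, was at least 2.54-fold higher, ZNF655 at least 2.29-fold and PATE2 at least 2.22-fold, the last above background on 1 of 2 ATF6b arrays, and MPPED2 passed (adjusted p = 0.0377) while not well above background in either group. With normexp PON3, ZNF655 and PATE2 had log2 changes between -0.024 and -0.0036, and none of these 4 passed. The offset of 50 in normexp is close to the median signal of an array (50.3 to 59.8 intensity units). It pulls changes of dim genes toward 0, so small normexp values of dim genes do not tell whether those genes differed. Of the 19 genes higher with ATF6b, 3 were below background in both groups and 13 had only a bound; of the 20 lower ones 17 were measured in both groups. With normexp 11 of the 19 higher ones kept their direction and 1 passed, against 20 and 19 of the 20 lower ones. With only probes above background on all 6 arrays, 5 genes were higher and 26 lower.

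Lists gave 6 calls between ATF6b and ATF6a with camera's preset correlation and 0 with an estimated one, where 1 list had an unadjusted p under 0.05. Interferon genes had a median of -0.82 (2 of 14 lower over all genes and 10 lower adjusted over the list alone, adjusted p = 2.1e-11, and adjusted p = 0.176 with an estimated correlation). IFIT1 had a value of -1.77 ± 0.20 and IFI44 of -1.91 ± 0.18, and neither passed (adjusted p = 0.0775 and 0.0514). Absorptive markers had a median of -0.20 (0 genes past over all genes, 1 lower adjusted over the list alone, adjusted p = 0.0139, and adjusted p = 0.388 with an estimated correlation), with KRT20 at -1.37 ± 0.49 (adjusted p = 0.301). This median was 0.095 with arrays scaled on spiked-in control RNA, where the median of all genes was 0.26. Cell cycle genes had a median of 0.20 (0 past, 1 higher adjusted over the list alone, adjusted p = 0.000220, and adjusted p = 0.388 with an estimated correlation). NF-kB and chemokine genes had 0.23 (0 past, 3 higher adjusted over the list alone, adjusted p = 0.00109, and adjusted p = 0.467 with an estimated correlation), with CXCL1 at 0.65 ± 0.08 (adjusted p = 0.0997). Heat shock genes had 0.22 (0 past by either adjustment, adjusted p = 0.00336, and adjusted p = 0.388 with an estimated correlation). Sterol and fatty acid synthesis genes had 0.16 (0 past by either adjustment, adjusted p = 0.00109, and adjusted p = 0.481 with an estimated correlation), with HMGCS1 at 0.59 ± 0.17 (adjusted p = 0.258).

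ER chaperones and folding enzymes had a median of -0.04 between ATF6b and ATF6a (adjusted p = 0.103), with 0 of 19 genes past the test over all genes and 4 lower adjusted over the list alone: CRELD2 at -0.70 ± 0.09, PDIA4 at -0.62 ± 0.10, HSP90B1 at -0.50 ± 0.10 and P4HB at -0.36 ± 0.07. Goblet markers had a median of -0.11 (adjusted p = 0.0584). The medians were 0.04 for ER-associated degradation (adjusted p = 0.880; 1 gene lower adjusted over the list alone), 0.05 for ER translocation (adjusted p = 0.172), 0.01 for the PERK-ATF4-CHOP arm (adjusted p = 0.692) and 0.07 for mucin O-glycosylation (adjusted p = 0.683). Enteroendocrine markers had -0.21 (adjusted p = 0.339), and stem cell and Wnt targets -0.04 (adjusted p = 0.223; 1 gene higher and 1 lower adjusted over the list alone). The p53 list had 0.02 (adjusted p = 0.811) and non-epithelial markers -0.03 (adjusted p = 0.351; 2 genes higher adjusted over the list alone). Of these 10 lists 0 held a gene past the limma test over all genes, and the ER-associated degradation, p53 and non-epithelial lists had medians opposite in sign to their test.

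The 39 calls needed all 6 arrays in the fit, and limma called no gene when any 1 of them was left out. An untransfected array left out does not alter the fold changes of ATF6b against ATF6a. It changes only the estimate of the spread and its degrees of freedom. The loss of calls there does not show that they relied on the values of that array. The count was also 0 with the slide row as a block, without the filter on dim probes and with only these groups in the fit (3298, 3638 and 2984 genes at an unadjusted p under 0.05), and 336 with normexp, 229 with an intensity trend and 653 with spike-in scaling.

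**Figure D2:**
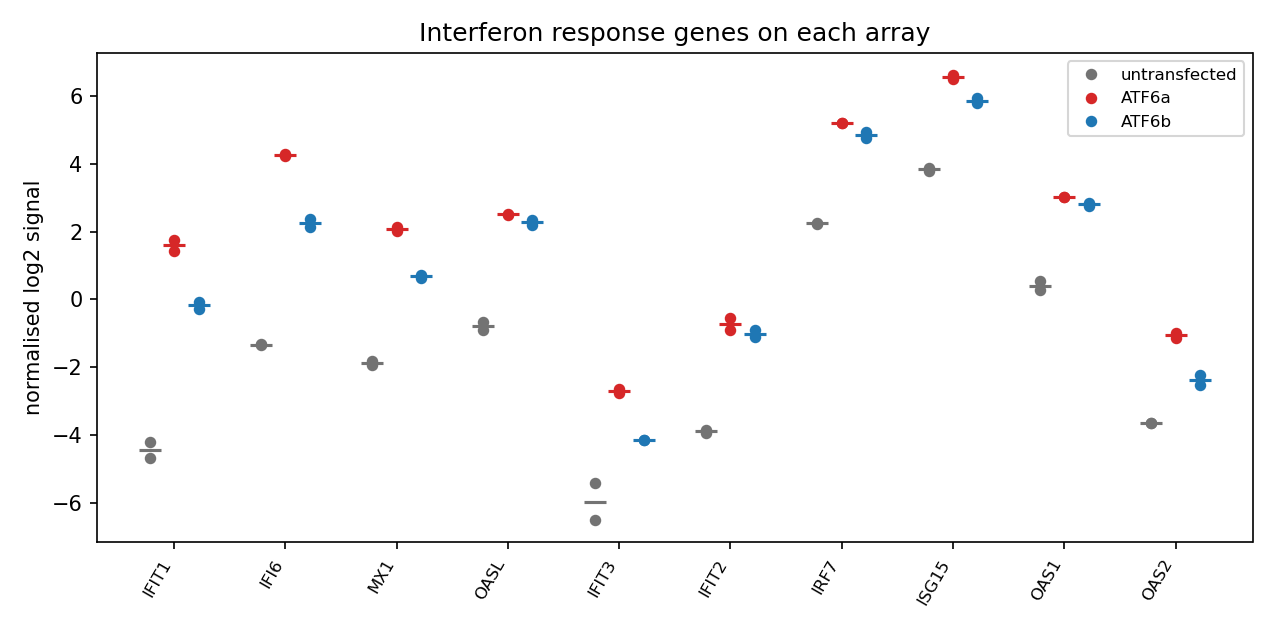
Log2 signal relative to the array's 75th percentile for the 10 of 14 measured interferon-response genes with the largest change with ATF6a, with 1 dot per array and a bar at the group mean. Both ATF6a arrays lie above both untransfected arrays for all 10 genes. Genes for which both ATF6b arrays lie below both ATF6a arrays include IFI6 and MX1, which passed the test over all genes, and IFIT1, which did not.

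Both sets of fold changes against untransfected cells were then compared across genes, which are not independent replicates. The arrays of ATF6a and ATF6b samples correlated at 0.992 to 0.994 across genes, replicates of a group at 0.995, and overexpressing with untransfected arrays at 0.922 to 0.935. The fold changes of ATF6a and ATF6b had a Pearson correlation of 0.970 and a Spearman correlation of 0.962 over 22573 genes, and the slope of ATF6b on ATF6a was 0.904. Both were computed against the same 2 untransfected arrays, and unchanged groups that share controls gave a correlation of 0.50 in 100 simulated sets. The covariance was 1.40 against 0.0245 simulated. The sign was the same for 91.6% of genes, against 66.7% simulated. In both comparisons 6843 genes were called higher and 6651 lower, and 5 were called in opposite directions. Independent lists of these sizes would share 2550 and 2413, without the shared controls, and unchanged groups with shared controls shared a mean of 0.01 and 0.01, without any effect. With 1 untransfected array for each comparison, so that none was shared, the correlation over 22561 genes was 0.942 or 0.938, the covariance 1.38 or 1.37 and the share of equal signs 88.2% or 88.5%. Calls were not made on this split, so part of the excess in shared calls could come from the shared controls.

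**Figure D3:**
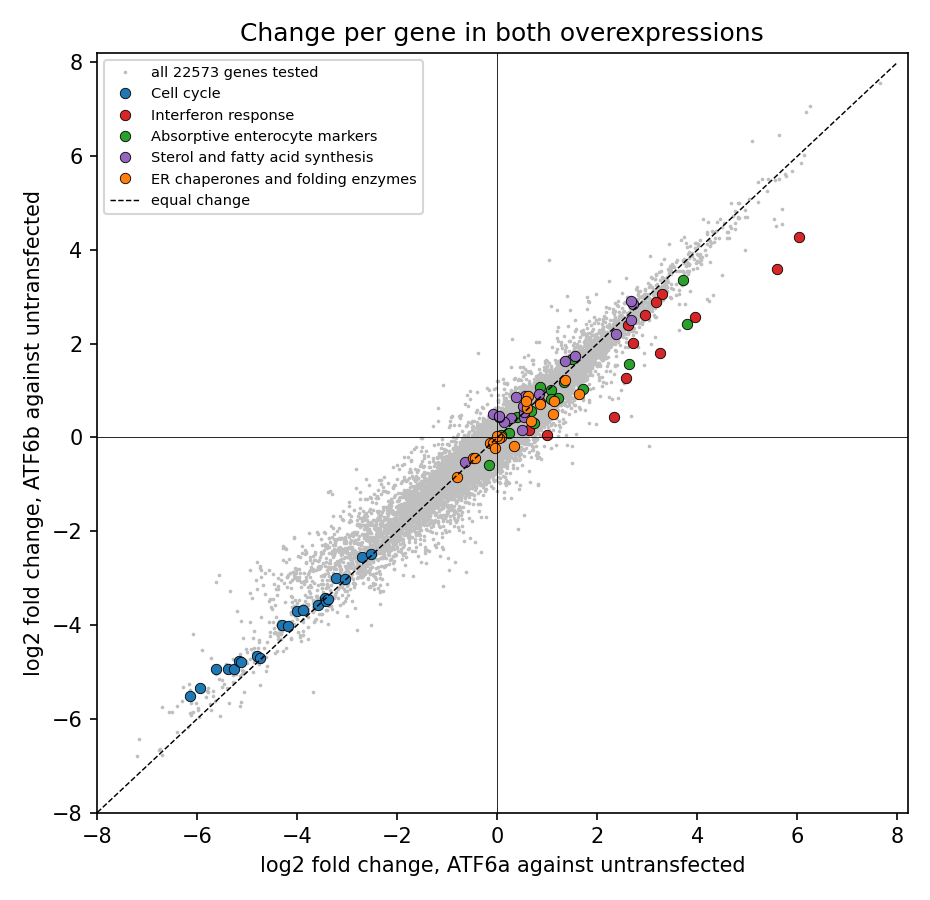
Log2 fold change of each tested gene with ATF6b against its log2 fold change with ATF6a, both relative to untransfected cells, with the members of 5 lists in colour. The points follow a line of slope 0.904 (Pearson correlation 0.970 across genes, against 0.50 simulated for shared controls alone).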

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

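The tests of the untransfected cells' treatment, of array scaling and slide place, and of a single library were fixed before their results were seen; the spike-in scaling they use, its median not taken relative to all genes and the test of a different response to transfected material were chosen afterwards.

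ATF6b and ATF6a samples were set against each other with a test of the difference itself, in which 39 genes differed. The list medians that differed by camera's preset correlation were -0.202 for absorptive markers, 0.197 for cell cycle genes, -0.824 for interferon genes, 0.234 for NF-kB and chemokine genes, 0.218 for heat shock genes and 0.155 for sterol and fatty acid synthesis genes, and 0 of the 16 lists differed in camera with an estimated correlation, where 1 had an unadjusted p under 0.05. The named genes that differed on the log2 scale were TMEM151B (2.76), PATE2 (2.16), ZNF655 (1.43) and PON3 (1.38) among those higher with ATF6b, and OTP (-3.21), XAF1 (-2.21), IFI6 (-2.00), KLHDC7B (-1.53) and SCARF2 (-1.48) among those lower. The values of PATE2, ZNF655, PON3 and OTP include signal below background, so that only a bound holds for them (at least 2.22-fold, 2.29-fold, 2.54-fold and 5.79-fold), and with normexp background correction the first 3 had log2 changes of -0.024, -0.0051 and -0.0036. MPPED2 passed with an adjusted p of 0.0377 while above background in neither group. All these gene calls ended when any 1 of the 6 arrays was left out. Without an untransfected array the fold changes stayed as they were, and only the estimate of the spread and its degrees of freedom changed.

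Both overexpressing groups stood apart from untransfected cells in 15262 and 14686 genes. A single shift per array as the whole cause was argued against by scaling on spiked-in control RNA, which kept the counts at 69.8% and 72.1% of those values. That scaling also changes the spread between replicates, on which the counts depend, and does not test scaling that varies with intensity. Quantile normalization, which varies with intensity, gave counts of 15545 and 14855. Untransfected cells without butyrate stay possible, since their titles read Tx-, which may mean no transfection or no treatment, although their labels state it: of 11 measured genes that histone deacetylase inhibitors are known to raise (10 of them in no other list), 54.5% rose in both comparisons against 35.9% of other genes (Fisher's exact test, two-sided p = 0.218), with TUBB3 (4.07 and 3.70) higher but TXNIP (-3.11 and -2.43) and H2BC21 (-1.01 and -1.02) lower. Slide place also cannot be told apart from group, since each group had its own column and the dimmest of 8 spike-ins differed by 0.695 on the log2 scale, although the other 7 stayed within 0.32. The overexpressed proteins and transfection itself remain open too, untested, because no group received an empty vector.

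The interferon list stood higher with ATF6a than with ATF6b by camera's preset correlation, with 2 of 14 genes past the test and adjusted p = 0.176 with an estimated correlation. A single library as the cause was argued against by a list median that stayed between -0.884 and -0.764 when each overexpressing library was left out in turn. Array scaling as the whole cause was argued against by a median of -0.527 under spike-in scaling and, relative to all genes, of -0.761 under quantile normalization. A different response to the transfected material could account for the pattern and stays open, because the NF-kB and chemokine list, with a median of 0.234, did not move with the interferon list but reports only part of such a response. A difference between the proteins themselves was not tested apart from this.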

How the results depend on the processing

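Scaling on spiked-in control RNA and keeping outlier spots were chosen after the data were seen; the other alternatives were fixed before. The replicate numbers, which were also the slide rows, were not taken as pairs (correlations of replicate differences between groups 0.109, 0.0577 and 0.0699), and with the replicate number as a block the counts were 15142, 14475 and 0 for ATF6a and ATF6b against untransfected and ATF6b against ATF6a (3298 genes at an unadjusted p under 0.05 in limma for the last, lowest adjusted p 0.0646). Against untransfected, the counts stayed within 1.5 times of 15262 and 14686 under every alternative run, from 10653 to 15774 for ATF6a and from 10591 to 15503 for ATF6b, and were 13359 to 14898 and 12238 to 14523 with 1 array left out. ATF6b against ATF6a gave 336 genes with normexp (68 higher, 20 shared with the 39), 0 without a filter (3638 at an unadjusted p under 0.05), 229 with an intensity trend (32 shared), 0 with only those groups (2984) and 653 with spike-in scaling (592 higher, 33 shared), and 0 to 0 with 1 array left out (2107 to 3501). Fewer arrays leave fewer residual degrees of freedom, and an untransfected array left out does not alter these fold changes; for the other settings the cause was not tested. Spike-in scaling moved the median of all genes to 0.26 for ATF6b against either group, and 65.6% of its calls against untransfected were higher instead of 49.6%. Lists called fell to 0, 0 and 0 with an estimated correlation, rose to 7 with spike-in scaling for ATF6b against untransfected (the cause was not tested), and ranged from 4 to 4, 4 to 4 and 5 to 9 with 1 array left out. The correlation of both fold changes was 0.978 with normexp, 0.929 without a filter, 0.975 with probes above background on all 6 arrays and 0.957 to 0.970 with 1 array left out. Signs reversed with normexp for PATE2 (-0.024), ZNF655 (-0.0051), MPPED2 (-0.036, below background in both groups) and PON3 (-0.0036), and for APOA4 in ATF6b against untransfected (-0.013). The offset of 50 in normexp pulls changes of such dim genes toward 0, so these signs do not tell whether the genes differed. With spike-in scaling the sign reversed for the absorptive list between ATF6b and ATF6a (0.095). This scaling shifts all genes of an array by the same amount. The list median stayed below the median of all genes, 0.095 against 0.26, as in the main fit (-0.202 against -0.032). The reversed sign therefore came from the shift of all genes. Direction and call held under all alternatives for 80 of 85, 78 of 86 and 28 of 75 named genes in the 3 comparisons. They held for 12, 9 and 4 of the 16 lists with the estimated correlation left aside. That version, on 3 residual degrees of freedom, ended every list call. Signal over background limits folds of dim genes to bounds.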

Other observations

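Gene families were grouped by symbol and tested only after the data were seen, and narrowed to protein-coding genes after a first run had been seen. Fisher's exact test (one-sided) set each against all other protein-coding genes, over 426 tests of 213 families of at least 8 measured genes. The test counts genes as independent, although members of a family can move together, so its p-values can be too small. Camera estimated a correlation of 0.18 between the genes of the cell cycle list. MCM2, MCM3, MCM5, MCM6 and MCM7 also stand in that list, so the MCM family below is not separate evidence. In the background 36.5% of 13759 genes rose in both overexpressing groups and 30.0% fell in both. Replication-dependent histone genes, which are expressed as DNA is copied, fell in both groups in 46 of 61 members and rose in 6 (medians -1.53 with ATF6a and -1.70 with ATF6b, adjusted p = 1.3e-10), among them H3C2 (-5.65 and -5.62) and H2AC13 (-4.13 and -4.27); probes may also detect near-identical members, which leaves the number of independent genes open, and across the scalings the medians stayed between -1.76 and -1.37. Centromere proteins (CENP) fell in 18 of 20 (-2.96 and -2.91, adjusted p = 7.9e-06), nucleoporins (NUP) in 18 of 21 (-1.09 and -0.88, adjusted p = 2.0e-05) and MCM replication genes in 9 of 9 (-3.22 and -3.04, adjusted p = 0.00168). Mitochondrial ribosomal proteins fell in 32 of 48 members of the large subunit (-0.63 and -0.60, adjusted p = 2.0e-05) and 18 of 28 of the small one (-0.49 and -0.47, adjusted p = 0.0111).

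Mucin genes (MUC) rose in both groups in 8 of 8 measured members (medians 2.34 and 2.06, adjusted p = 0.0148), including the membrane mucins MUC13 (3.31 and 3.40) and MUC17 (2.62 and 2.59). RAB genes of vesicle traffic rose in 29 of 50 members (0.48 and 0.54, adjusted p = 0.0484), with RAB37 at 3.42 and 3.31 and RAB26 at 2.73 and 2.67. CEACAM genes rose in 8 of 10 members (2.53 and 2.68) and keratins in 20 of 32 (0.94 and 0.75), which did not pass as families (adjusted p = 0.125 and 0.0696). These medians kept their sign under each scaling. Families passed in 2 tests for a rise and in 12 for a fall. Zinc finger genes (ZNF) also passed for a fall, in 155 of 400 members (medians -0.21 and -0.16, adjusted p = 0.00672), but the median turned positive, up to 0.11, under another scaling.

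In total 492 genes were above background on all 4 overexpressing arrays and neither untransfected array, and 726 the reverse; these counts ask for different numbers of arrays and have no value for unchanged groups beside them, so they give no direction. Among the 20 genes lower with ATF6b than with ATF6a were further interferon-inducible genes, chosen after their values were seen: IRF9 (-1.36 ± 0.10), BST2 (-1.28 ± 0.09), SAMD9L (-1.32 ± 0.11), IFITM1 (-1.04 ± 0.09) and RSAD2 (-1.03 ± 0.08).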
